A study of Mus musculus with 2 samples.

How the data were processed

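The series holds 2 miRNA arrays of epididymal adipose tissue, the fat pad that lies against the epididymis, from male C57BL/6J mice. Per the labels, feeding started at 8 weeks of age and lasted 8 weeks, 1 array came from mice on a normal diet with 5% fat and 1 array from mice on a diet with 60% of its energy as fat. The labels do not say how many animals gave RNA to each array. The comparison therefore has 1 array per diet, and its precision is limited by that number: no p-value, standard error or test across animals could be made. The arrays were the positions numbered 1 and 2 of a slide, per the file headers, so diet and array position cannot be told apart.

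Per the labels, total RNA was labelled with the dye Cy5 and hybridised to a 3D-Gene array in 1 colour. Per the file headers, each scanner file gives the median intensity of each spot and a median intensity of the background around it, merged from several scanner gains. The scanner software is not given in the sources used here. Each array had 3200 spots: 1900 named miRNA probes with 1 spot each, 896 blank spots, 174 spots without a probe, and controls. Of the miRNA probes, 12 were named for several miRNAs at once, and these were given no value under a single name. The authors' deposited table of processed intensity values was compared with the scanner values: each column was the spot median minus the trimmed mean of that array's blank spots, times 1 factor (1.858 for the normal-diet array and 1.556 for the high-fat array). The largest deviation from that line was 3.1e-06. The median of the listed values was 25 on both arrays. A miRNA was listed exactly where its spot lay above the blank mean plus 2 SD, for all 1900 probes, so the scale of these values is linear, with no centring per miRNA and no log.

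Spot medians were corrected here for background with limma's normexp method (offset 50), scaled by quantile normalisation over the 1900 miRNA probes, and put on a log2 scale; the log2 values are not the authors' own. The difference of a miRNA is the high-fat value minus the normal-diet value. A miRNA counted as detected above the mean plus 2 SD of the blank spots, with 5% of blanks trimmed at each end. The scanner's flag could not serve for this, since it read the same for all 3200 spots of an array, blanks included. The plan was to run normexp on the spot and its local background. That background column followed the light of the spot itself: over 219 and 240 spots with a net signal above 100, it held a median of 0.614 and 0.579 of the net signal (r across spots 0.954 and 0.97). The trimmed blank mean, which the authors' deposited values also use, was therefore taken as the background, and the plan's literal reading was kept as an alternative. This departure was decided after the differences under both backgrounds had been seen, and the literal reading turns several directions.

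The offset of 50 shrinks differences of dim probes. A pair of arrays was simulated from the signals of the normal-diet array, with miRNAs changed by known amounts. The noise was that of spike-control and blank spots within an array, so it does not cover differences between samples. A 4-fold rise among bright miRNAs was returned with a median log2 difference of 0.89 and a 4-fold fall with -1. A 2-fold rise was returned with 0.51 and a 2-fold fall with -0.33. The size rule of 2-fold was passed by only 12 of 28 and 15 of 29 bright miRNAs changed 4-fold up and down, and by 1 of 26 and 2 of 22 changed 2-fold. The counts of miRNAs past 2-fold therefore miss most changes near that size. Of 1079 unchanged miRNAs, dim ones included, 0 passed. Of 100 simulated lists without a change, 1 lay outside the central range of random lists, and a list of 8 miRNAs shifted by 0.5 lay at percentile 100. These lists were drawn at random with independent noise. The check therefore does not cover lists whose members are transcribed together, for which the percentiles below can be more extreme.

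The 22 miRNA lists, the size rule of 2-fold, the first 11 alternatives below and the rule for the miRNAs named in the text were fixed before the data were examined. The lists were compiled from general knowledge, with no source consulted. Members were matched by name, and 4 had no probe of their own (miR-465a-3p, miR-199a-3p, miR-486a-5p and miR-486b-5p). Only members detected on both arrays enter a list's median. Its percentile is its place among the medians of 10000 random lists of the same size, drawn from miRNAs detected on both arrays in the same of 10 classes of mean signal. It describes these arrays and is no p-value. Several lists overlap: all 7 miRNAs of the list of those reported higher on a high-fat diet also stand in another list, as do 7 of the 20 adipocyte differentiation miRNAs and 11 of the 15 lipid and insulin signalling miRNAs.

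The rule for names took the 8 largest differences in each direction among miRNAs of at least the median signal that passed 2-fold under quantile, 75th percentile, median and no scaling. It also took the 5 brightest miRNAs, up to 4 members of each list with the largest difference, and up to 4 miRNAs per direction detected on 1 array only. For the last kind a lower bound of the fold is given: the normalised value on the array that detected it, against the higher of the lowest detected value on the other array and the probe's own value there. Other miRNAs named in the text were chosen after their values were seen.

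The first 11 alternatives were plain subtraction of the blank mean, no subtraction, a smaller offset of 16, scaling by the 75th percentile, by the median or not at all, cyclic loess, the authors' deposited values, detection at 3 SD, no detection filter, and only the brighter part of the detected miRNAs. A further 3 became alternatives after the data were seen. These were normexp with the local background, which the plan had named for the main values, scaling to the 2 spike controls, and counts without the epididymis, testis and miR-200 lists. Neighbouring miRNA genes were taken from a RefSeq gene table of the GRCm38.p6 assembly, which served only for names and neighbours (genes at most 10000 bases apart); 1794 of the 1900 probes matched a gene in it. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.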

Results

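The question was how miRNA levels in epididymal fat of mice differ between a normal and a high-fat diet. Total RNA from this fat pad was hybridised to 2 single-colour arrays, 1 per diet, each with 1900 miRNA probes. On the normal-diet array 1370 miRNAs were detected (72.1%), and on the high-fat array 1510 (79.5%). Both arrays detected 1339 miRNAs, 171 were detected on the high-fat array only, 31 on the normal-diet array only, and 359 on neither. The blank spots averaged 75.65 on the normal-diet array and 69.24 on the high-fat array, and detected miRNAs lay a median of 13.5 and 16.1 intensity units above them. Normalised log2 intensities correlated with r = 0.965 across the 1339 miRNAs, which are not independent replicates. With 1 array per diet, no difference below has a replicate check. The only error that can be given is that of repeated control spots within the arrays: over 8 spots each, a single-spot log2 difference varied with an SD of 0.11 to 0.197.

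miR-34c-5p, a miRNA abundant in testis and in ciliated epithelium, was the miRNA with the largest difference among those detected on both arrays: its normalised intensity was 59.64 on the normal-diet array and 1179 on the high-fat array (log2 difference 4.31). This difference was 7.89 by plain subtraction, 7.67 in the authors' deposited values and 1.67 with the local background. The erythrocyte miRNAs miR-451a and miR-144-3p were lowest relative to normal diet, at 4957 against 1080 (-2.20) and 475.5 against 118.5 (-2). In all, 17 miRNAs were at least 2-fold higher and 10 at least 2-fold lower on the high-fat array; 15 and 10 of them did so at or above the median signal under each of 4 scalings. After miR-34c-5p the highest were miR-335-5p (137.3 against 466, log2 difference 1.76), which is encoded in an intron of Mest, a gene of adipose tissue growth, and which was at 0.13 with the local background, then miR-6378 (1.55), miR-6955-5p (1.53), miR-706 (1.45), miR-34b-3p (1.44), miR-3090-5p (1.38) and miR-3102-5p (1.35). This order depends on the processing: miR-34b-3p was at 5.26 and miR-335-5p at 2.52 by plain subtraction, and at 5.24 and 2.32 in the authors' deposited values. On the lower side, after the erythrocyte miRNAs, came miR-378a-3p (-1.66), miR-378b (-1.49), miR-193b-3p (-1.42), miR-193a-3p (-1.41), miR-378d (-1.39) and miR-378c (-1.38). With the local background miR-378d was at 0.35, and miR-378b (-0.63), miR-193b-3p (-0.73), miR-706 (0.76) and miR-34b-3p (0.89) did not reach 2-fold. With spike-control scaling miR-193b-3p (-0.87), miR-378d (-0.95) and miR-378c (-0.93) did not. The miR-378 probes have near-identical targets and could not be read as separate measurements. Without the epididymis, testis and miR-200 lists, 12 miRNAs were at least 2-fold higher and 10 lower. Under quantile scaling the median of all miRNAs detected on both arrays was -0.04, so most of them had a value below 0. Scaling to the spike controls moved this median to 0.35 and gave 45 higher and 5 lower. With the local background, 24 were higher and 18 lower, of which only 5 and 6 were among the miRNAs counted above, and 26 of the 85 named miRNAs detected on both arrays had the other sign.

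**Figure D1:**
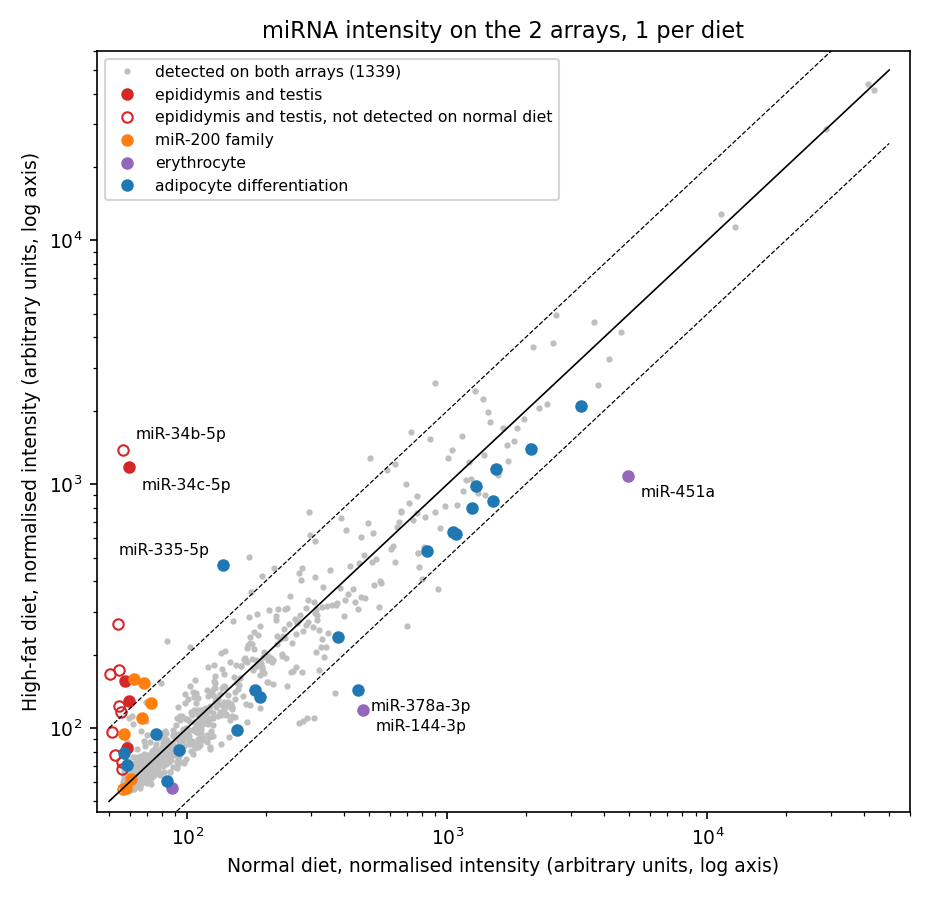
Normalised intensity of each of the 1339 miRNAs detected on both arrays, with the normal-diet array on the horizontal and the high-fat array on the vertical axis (arbitrary units, log axes, 1 point per miRNA); open red circles are epididymis and testis miRNAs not detected on the normal-diet array. The solid line marks equal values and the dashed lines a 2-fold difference. miR-34c-5p and miR-34b-5p lie far above the lines, and miR-451a and miR-144-3p below them.

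Epididymis and testis miRNAs were the list furthest toward high-fat diet. Of 14 members with a probe, 4 were detected on both arrays and the other 10 on the high-fat array only. The 4 had a median log2 difference of 1.28 (percentile 100 among random lists of like signal), or 1.12 with the 10 others at their bounds. miR-34b-5p stood at 1386 on the high-fat array and below the detection limit on the normal-diet array, which made it at least 24.4-fold higher. The related miR-449a-5p was at least 4.7-fold higher, and miR-743a-3p and miR-741-3p, of a cluster on the X chromosome known for expression in testis, at least 3.06-fold and 2.94-fold. miR-34c-3p (1.12) and miR-871-3p (0.50) were also higher. The miR-200 family, typical of epithelial cells and uncommon in fat cells, was higher as well: 6 of its 7 members detected on both arrays were above their normal-diet value, with a median of 0.72 (percentile 100). They included miR-200a-3p (62.42 against 159.1, log2 difference 1.35), miR-200b-3p (1.17), miR-141-3p (0.80) and miR-429-3p (0.72). Both medians stayed above 0 under all scalings and backgrounds tried. The normal-diet values lie near the offset, and these medians were larger with an offset of 16, at 2.14 and 1.26, and by plain subtraction, at 4.64 and 2.24. They were smaller with the local background, at 0.48 and 0.14, where miR-34c-3p was at 0.07, miR-200a-3p at 0.09 and miR-200b-3p at 0.14.

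**Figure D2:**
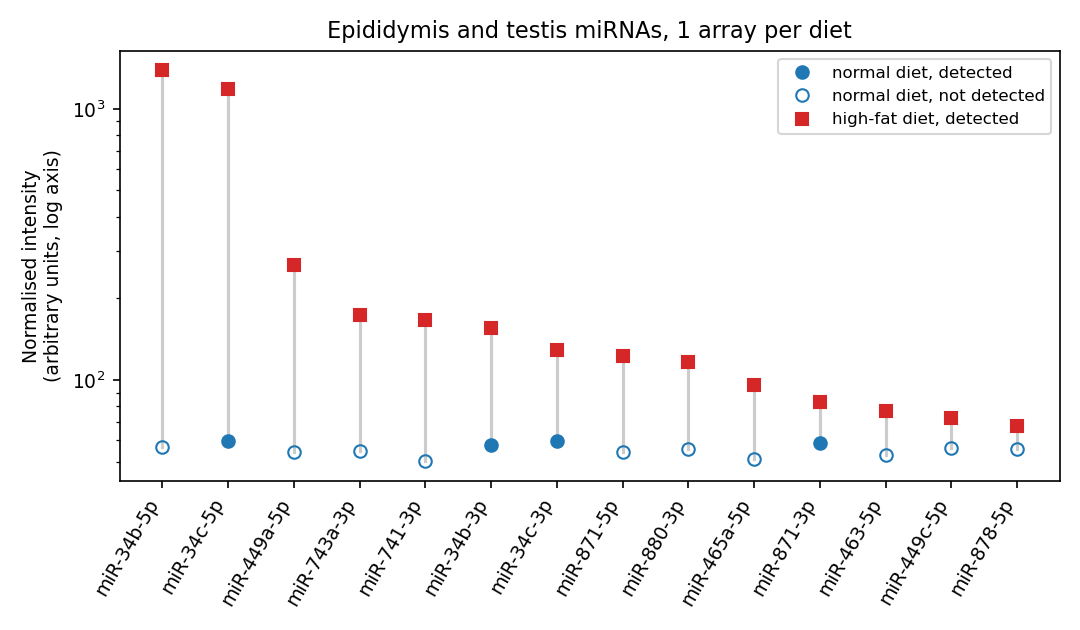
Normalised intensity of the 14 epididymis and testis miRNAs with a probe, on the normal-diet array (blue circles, open where not detected) and the high-fat array (red squares); the vertical axis is in arbitrary units on a log scale, and grey lines join the 2 arrays. Each high-fat value lies above the normal-diet value, from miR-34b-5p at 1386 to miR-878-5p at 67.84.

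Erythrocyte miRNAs were lower on the high-fat array under every scaling. The 3 with a probe of their own had a median of -2 (percentile 0, that is, below all 10000 random lists). They come from neighbouring genes, so this percentile does not rest on independent members. The dimmest, miR-144-5p, stood at 87.36 and 56.57 (-0.63). It was at -3.5 by plain subtraction, -3.41 in the authors' deposited values and -0.06 with the local background. The probe shared by miR-486a-5p and miR-486b-5p, also of this list, was lower by less (-0.41). Of 17 leukocyte and inflammation miRNAs detected on both arrays, 15 were lower, with a median of -0.15 (percentile 0.315), although the median was 0.29 with spike-control scaling and -0.00628 (percentile 46.2, 7 of 17 higher) with the local background. The lymphocyte miRNA miR-150-5p was 2.55-fold lower (267.6 against 104.9, -1.35), but at -0.89 with spike-control scaling and 0.34 with the local background. The myeloid miR-223-3p was at -0.89, and miR-146a-5p and miR-146b-5p, which restrain inflammatory signalling, at -0.66 and -0.65, although the local background gave miR-146a-5p 0.28. The endothelial miR-126a-5p (-0.76) and miR-126a-3p (-0.57) were lower, with a median of -0.67 (percentile 3.78), but the median was 1.28 with the local background, and both were higher.

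Adipocyte differentiation miRNAs were lower on the high-fat array as a group: 16 of 20 members lay below their normal-diet value, 14 with spike-control scaling, and the median was -0.55 (percentile 0). Over members of at least the median signal it was -0.62, with the leukocyte list at -0.51 and the anti-adipogenic list at -0.50. The fall was thus not particular to this list, although the lists of GC-rich probes (0.22) and of the miR-17 to miR-92 clusters (0.34) were higher at that signal. On the same array the epididymis and testis list had its median at 1.28 and the erythrocyte list at -2. miR-378a-3p, encoded within the metabolic coactivator gene Ppargc1b, had the lowest value (452.3 against 142.7). miR-30a-5p (-0.81), miR-107-3p (-0.79) and miR-103-3p (-0.72), of which the last pair are linked to insulin signalling, followed among the abundant members, whereas miR-335-5p was higher at 1.76 (0.13 with the local background). The list's median was -0.03 (percentile 35.4) with the local background, where miR-30a-5p was at 1.32. The brown and beige fat list had a median of -0.21 (percentile 2.76) over 9 members, 0.25 with spike-control scaling and -0.01 (percentile 51.6) with the local background; its 3 members past 2-fold were miR-193b-3p, miR-193a-3p and miR-365-3p (919.6 against 372.6, -1.30), with miR-30b-5p at -0.23 (1.81 with the local background). Only miR-193a-3p (-1.10) passed 2-fold with spike-control scaling, and only miR-193a-3p (-2.43) and miR-365-3p (-1.91) with the local background. miR-193b and miR-365 share a gene cluster known to be induced in brown fat cells. The 12 anti-adipogenic miRNAs had a median of -0.11 (percentile 4.06), 0.27 with spike-control scaling and 0.01 with the local background. Dim members hold this median near 0: it was -0.50 (percentile 0.14) over the brighter members and -0.65 (percentile 0.15) in the authors' deposited values. The lowest of them was miR-130a-3p (-0.97), which targets Pparg, followed by miR-145a-5p (-0.63), miR-27b-3p (-0.56) and miR-27a-3p (-0.51); with the local background miR-130a-3p was at 2.01, miR-145a-5p at 3.48 and miR-27b-3p at 0.47. Of 13 lipid and insulin signalling miRNAs, 11 were lower (median -0.30, percentile 1.39), and miR-34a-5p was 2.04-fold higher (176.3 against 360.6, 1.03), or 0.20 with the local background.

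Of 7 miRNAs listed as reported higher in white fat of animals on high-fat diets, 6 were lower here, among them miR-142a-3p (-0.58) and miR-21a-5p (2053 against 1434, -0.52). Their median was -0.52 (percentile 0.03), but 0.09 with 4 of 7 higher with the local background, where miR-21a-5p was at 0.28. The list of those reported lower went both ways. Of its 6 members with a probe, 5 were detected on both arrays, with a median of 0.08 (percentile 86.7): miR-192-5p was at 0.88, miR-1a-3p at 0.13, miR-203-3p at -0.20 and miR-30a-3p at -0.66. The other, miR-122-5p, was detected on the normal-diet array only, and with it at its bound the median was 0.0176. All 5 were higher with the local background.

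miRNA families differed in both directions. The miR-17 to miR-92 clusters, tied to cell proliferation, had a median of 0.34 (percentile 99.4) under quantile scaling and above 0 under the other scalings, with 7 of 12 members higher, among them miR-19a-3p (102.4 against 214.1, log2 difference 1.06), miR-19b-3p (296.2 against 616.6, 1.06), miR-18a-5p (0.95) and miR-17-5p (0.57). The 5 lower members included miR-106b-5p (-0.56), miR-93-5p (-0.08) and miR-25-3p (-0.05), which form a cluster of their own. With the local background this median was -0.11, and miR-19a-3p was at 0.00782, miR-19b-3p at -0.0122 and miR-17-5p at -0.29. miR-19b-3p was just under 2-fold with 75th percentile (0.94) and median scaling (0.99) and in the authors' deposited values (0.97). The 5 miR-30 miRNAs were all lower under every scaling (median -0.56, percentile 1.7), with miR-30d-5p at -0.65, miR-30e-5p at -0.56 and miR-30c-5p at -0.41, but had a median of 1.14 with the local background, with 4 of 5 higher. The miR-23, miR-27 and miR-24 clusters had a median of -0.45 (percentile 1.2), with 6 of 7 lower, 4 of them with spike-control scaling, and miR-23b-3p at -0.53 and miR-23a-3p at -0.45. The local background gave this list -0.06 (percentile 31.1), with members far apart: miR-23b-3p at 3.00 and miR-23a-3p at 2.77, but miR-27a-3p at -2.64. The 3 miR-29 miRNAs were lower under every scaling (median -0.30, percentile 21.4), from miR-29c-3p at -0.49 through miR-29b-3p at -0.30 to miR-29a-3p at -0.22. All 9 let-7 miRNAs were lower under quantile scaling (median -0.21, percentile 19.4), while 2 were higher with spike-control scaling, 1 by plain subtraction and 4 with the local background. They included miR-98-5p (-0.60), let-7i-5p (-0.43), let-7e-5p (-0.27) and let-7b-5p (-0.26), of which the local background put let-7i-5p at 1.61 and let-7b-5p at -2.80. The miR-99, let-7 and miR-125 clusters had a median of -0.27 (percentile 14.6), or 0.04 with the local background. In them miR-99a-5p (-0.57), miR-125a-5p (-0.51) and miR-99b-5p (-0.51) were lower and miR-125b-5p was higher (0.40), whereas the local background gave miR-99a-5p 0.04, miR-99b-5p 0.25 and miR-125b-5p -0.77. In the authors' deposited values miR-125b-5p was at -0.10. The imprinted Dlk1-Dio3 cluster had a median of -0.08 over 22 members (percentile 1.26), with 19 lower, but all 22 were higher with spike-control scaling (median 0.30). The median of all miRNAs detected on both arrays was itself -0.04 under quantile scaling. With the local background the cluster's median was 0.00591 (percentile 63.6), with 12 of 22 higher. Its largest differences were those of miR-487b-3p (-0.50), miR-127-3p (-0.21), miR-300-3p (-0.20) and miR-329-3p (-0.17), with miR-487b-3p at 0.51 with the local background.

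Among markers of other tissues, stromal and smooth muscle miRNAs had a median of -0.38 over 9 members (percentile 2.51), 0.07 with spike-control scaling: miR-145a-5p, miR-143-3p (-0.59) and miR-10a-5p (-0.56) were lower, and miR-199a-5p was higher (0.50). The 4 detected muscle miRNAs had a median of -0.00185 (percentile 78.6), which was above 0 with median, cyclic loess, spike-control and no scaling; miR-133a-3p was at -0.11, miR-206-3p at -0.08 and miR-133b-3p at 0.08. In the liver list miR-192-5p (69.1 against 127.5) and miR-194-5p (0.54), which are also made in gut and kidney epithelium, gave a median of 0.71 (percentile 98.7), or 0.13 with the local background. The main miRNA of hepatocytes, miR-122-5p, lay near the blanks on both arrays, with a net signal of 2.01 on normal diet and 1.14, not detected, on high-fat diet.

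**Figure D3:**
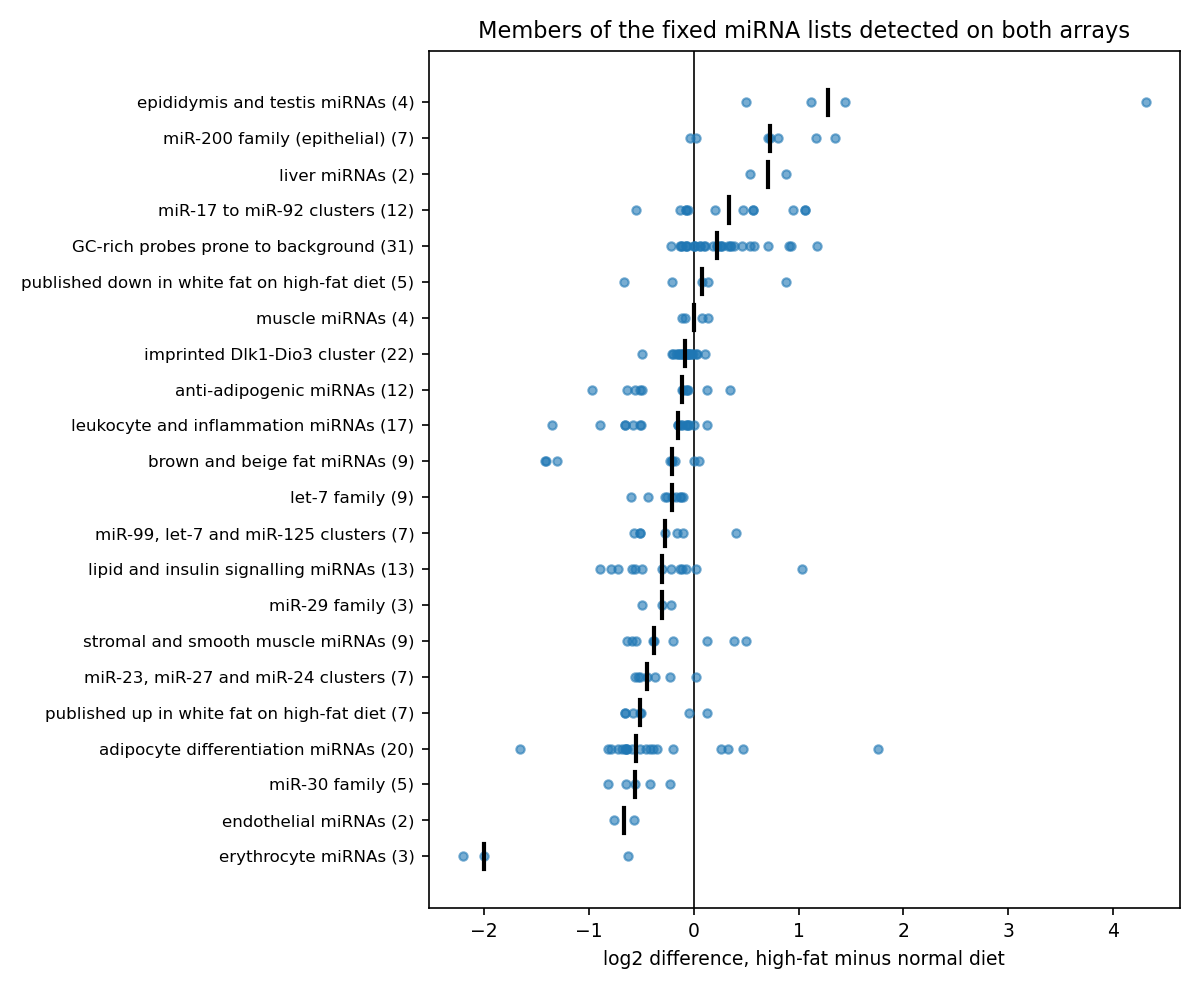
log2 difference (high-fat minus normal diet) of each member detected on both arrays for the 22 miRNA lists, 1 point per miRNA, with a black bar at the list's median and the number of members in brackets. Medians run from -2 for erythrocyte miRNAs to 1.28 for epididymis and testis miRNAs. With spike-control scaling the medians of the leukocyte, Dlk1-Dio3, anti-adipogenic, brown fat, stromal and muscle lists lie above 0; that of the muscle list does so with median, cyclic loess and no scaling too.

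The 5 brightest miRNAs were miR-5100, miR-3968, miR-6366, miR-3963 and miR-6412. Quantile scaling gives equal ranks equal values, so their closeness under it is set by the method; with cyclic loess miR-3968 was at 0.54 and miR-5100 at 0.39, and in the authors' deposited values miR-3963 was at -0.62. The 5 top probes of each array held 48% of the net signal on the normal-diet array and 46.2% on the high-fat array. GC-rich probes prone to background had a median of 0.22 over 31 miRNAs (percentile 100), with 22 higher, and this median stayed above 0 under all scalings. miR-709 was highest of them (723.9 against 1639, log2 difference 1.18), followed by miR-2137 (0.93), miR-2861 (0.91) and miR-3960 (0.70), but with the local background miR-709 was at 0.29 and miR-2137 at -0.08. miR-709 also stayed under 2-fold with 75th percentile (0.86), median (0.91) and no scaling (0.98) and in the authors' deposited values (0.78). Of the miRNAs detected on the normal-diet array only, none was bound to be more than 1.12-fold lower on the high-fat array: the bounds were 1.12-fold for miR-676-5p and 1.08-fold for miR-6936-5p, miR-3075-3p and miR-1a-1-5p.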

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

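The comparison of these probes was chosen after the miRNA results had been seen. The arrays carry 22 probes numbered from S-Probe1001 on that bear no miRNA name, and their meaning is not given in the sources used here. They entered no comparison, and 15 were detected on both arrays, above the blank spots. S-Probe1014 had a net signal of 1802 on the normal-diet array and 4240 on the high-fat array, a ratio of 2.35. S-Probe1017 was dim, at 3.072 and 9.044, a ratio of 2.94. S-Probe1020 went the other way, from 8.341 to 3.817. The controls named S-Probe26, S-Probe27 and S-Probe28, with 8 spots each, had log2 differences of -0.33, -0.27 and -0.47 in net signal, before scaling. The 2 spike controls were at -0.315 and -0.331 on the same measure, so this fall was not particular to those probes. No biological explanation was tested, and each numbered probe has 1 value per diet.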

How the results depend on the processing

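The blank background of the main values, the spike controls and the counts without the epididymis, testis and miR-200 lists were chosen after the data were seen. The local background was the plan's literal reading. No paired analysis was possible because each diet has 1 array, and leaving out a replicate was not possible for the same reason. With 75th percentile, median, cyclic loess and no scaling and with no subtraction, all 22 list medians and all 85 named miRNAs detected on both arrays moved by less than 1.5-fold, and so did the list medians with detection at 3 SD, no detection filter and the brighter miRNAs only. Of these 85 miRNAs, 19 shifted by over 1.5-fold by plain subtraction, 23 in the authors' values, 7 with offset 16 and 49 with the local background, where 26 had the other sign: miR-34c-5p was at 7.89 by plain subtraction and 1.67 with the local background, miR-335-5p at 0.13, miR-193b-3p at -0.73 and miR-378b at -0.63 with the latter. The count of miRNAs detected on both arrays was 670 for the brighter ones, by construction. By plain subtraction, which drops normexp along with its offset, 95 and 59 miRNAs were at least 2-fold higher and lower. In the authors' values, which also lack quantile scaling, they were 101 and 62. These counts cannot be put down to the offset alone. All 17 and 10 of the counts above were among those by plain subtraction, and 15 and 10 among the authors'. The higher count was 30 with offset 16 and 27 with no detection filter. By plain subtraction and in the authors' values, the list medians were 4.64 and 4.65 for epididymis and testis (2.14 with offset 16), 2.24 and 2.23 for miR-200, -2.61 and -2.77 for erythrocyte, and 1.80 and 1.72 for liver miRNAs. Spike-control scaling gave 45 higher and 5 lower, and medians above 0 for leukocyte (0.29), Dlk1-Dio3 (0.30), anti-adipogenic (0.27), brown fat (0.25), stromal (0.07) and muscle miRNAs (0.42). With the local background, 18 miRNAs were lower, and these medians took the other sign: miR-17 to miR-92 (-0.11), Dlk1-Dio3 (0.00591), the list reported higher on a high-fat diet (0.0927), miR-30 (1.14), endothelial (1.28), anti-adipogenic (0.00987), miR-99, let-7 and miR-125 (0.04) and muscle miRNAs (0.00555). So did, among named miRNAs past 2-fold, miR-19b-3p (-0.0122), miR-150-5p (0.34) and miR-378d (0.35). The medians of the epididymis and testis (0.48) and miR-29 (-0.997) lists moved by more than 1.5-fold there. The cause was not tested beyond the share of spot light in that background. Signal limits the rest: detected miRNAs lay a median of only 13.5 and 16.1 units above the blanks.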

Other observations

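The list medians and their percentiles at matched signal were fixed before the data were examined, while the use of them to weigh an explanation, and the other tests in this part, were chosen after the results had been seen. Beyond the fixed lists, the X-linked gene cluster around miR-741 held 20 further miRNAs with a probe: 14 were detected on the high-fat array only, 3 on both and 3 on neither. miR-743b-3p went from below the blanks to a net signal of 72.6, miR-883a-3p to 68.7, and miR-470-5p, detected on both arrays, from 5.52 to 63.4. The 14 were among 17 not detected on the normal-diet array. Of 485 other miRNAs outside the fixed lists and not detected on it, 141 were detected on the high-fat array (29.1%). Probes named for several miRNAs gave -0.41 for miR-486a-5p and miR-486b-5p, which red blood cells carry (98.87 against 74.55), and 0.42 for miR-199a-3p and miR-199b-3p. The other products of the miR-486 genes, miR-486a-3p and miR-486b-3p, were at 0.30 and -0.16.

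Epididymis and testis miRNAs were higher on the high-fat array, led by miR-34b-5p (1386) and miR-34c-5p (1179), with a list median of 1.28, or 0.48 with the local background. A defect of a region of the array is argued against by their spread, since the 9 members at least 2-fold higher, bounds included, lay in 8 of 32 blocks, and so is a general lift of dim probes: the 10 members not detected on normal diet had a median high-fat net signal of 71.7, against 0.507 for all 530 such miRNAs and a 99th percentile of 3.18 for random lists. Epididymis or testis RNA in the high-fat sample needs other miRNAs of those tissues too. Of the 20 miRNAs of the X-linked cluster outside the lists, 14 were detected on that array only, and the epithelial miR-200 family was also higher. Those 14 add little, because they neighbour list members already seen to be higher, and some, such as miR-741-5p, come from the same gene as a list member. Only miR-743b-3p (log2 bound 1.09) and miR-883a-3p (1.05) of them were bound to be at least 2-fold higher. A candidate explanation is epididymal tissue taken along with the fat pad. It stays a hypothesis, because expression of this cluster in the fat itself would give the same count, and diet and array position differ between the same 2 samples.

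The erythrocyte miRNAs miR-451a and miR-144-3p, of neighbouring genes, were lower on the high-fat array. The probe shared by miR-486a-5p and miR-486b-5p was lower by less (-0.41). Scaling as the whole cause of the fall of miR-451a and miR-144-3p is argued against. Over 6 scalings the smallest of their differences was -1.56. The 100 miRNAs nearest in signal had a median of -0.136 for miR-451a and -0.0239 for miR-144-3p. That none of these neighbours lay lower adds nothing, because both miRNAs had the largest falls of all those detected on both arrays. Less blood in the high-fat sample would also lower miRNAs of white blood cells. The fixed leukocyte list was at percentile 0.315 with quantile scaling but up to 3.57 over the 6 scalings and 46.2 with the local background, and immune cells resident in fat make these miRNAs too, so less blood stays an open explanation. An effect of diet on blood content or on red cell miRNAs was not tested.

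Adipocyte differentiation miRNAs were lower and GC-rich probes higher on the high-fat array. With the local background the adipocyte median was -0.03 (percentile 35.4, 10 of 20 higher), so that part of the pattern was lost there. The adipocyte median was -0.51 (percentile 0) with no subtraction. With the blank background, a trend with signal alone is argued against by percentiles of 0 and 100 at matched signal. RNA of another tissue added to the fat would lower all fat miRNAs alike; among members of at least the median signal, the adipocyte (-0.62), leukocyte (-0.51) and endothelial (-0.67) medians lay within 0.158 of each other, but the stromal median was -0.38 with 3 of 9 higher, up to 0.50 for miR-199a-5p, adipocyte members ran from -1.66 to 1.76, and the endothelial median was 1.28 with the local background. Such a dilution cannot be told apart from other causes, because the endothelial list has 2 members, an added tissue can bring stromal miRNAs of its own, and the rule for reading this test was changed after its value was seen. An effect of the background choice, a diet effect and a difference in RNA quality stay open, the last pair untested.

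Neighbouring miRNA genes had similar differences. Over 102 bright miRNAs in 36 genomic clusters, 77.3% of the variance of the log2 differences lay between clusters, against a median of 36.9% when differences were shuffled among miRNAs of like signal (percentile 100 of 10000 shuffles). Without the clusters of miR-451a, miR-200, miR-34 and miR-741 it was 72% against 36.3%. With the local background it was 35.7% against 36.6% (percentile 45.66), so the similarity was lost with that background. miR-143-3p (-0.59) and miR-145a-5p (-0.63) are one such pair, at -1.74 and 3.48 with the local background, while miR-451b (0.06) stood apart from miR-451a. With the blank background this is consistent with shared transcription of clustered miRNAs, and also with cross-hybridisation among similar members, which was not tested.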
